A study of Sus scrofa with 32 samples.

How the data were processed

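RNA from 3 tissues of 11 juvenile Ossabaw miniature swine was measured on 32 Affymetrix porcine arrays. The tissues were the left anterior descending coronary artery (LAD), the perivascular fat beside it (PVAT) and the descending thoracic aorta (TA). The lean group of 6 pigs ate a commercial low fat diet, and the obese group of 5 pigs ate a diet high in fat, fructose corn syrup and cholesterol, in each case for 16 weeks. Each pig gave 1 array per tissue, except pig 63, which had no TA array, so the groups held 6 and 5 arrays for LAD, 6 and 5 for PVAT, and 5 and 5 for TA. Replicates are separate animals. Per the labels the arteries were freed of fat and excess adventitia, and arteries and fat were extracted with different RNA kits.

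The deposited values are log2 expression summaries per probe set, which the authors made with the affy package for R, whose version is not given in the sources used here. The method of background correction and normalization is not given in the sources used here either. The deposited table holds 14327 probe sets. Every probe set reaches a log2 value of 6.64, the log2 of an intensity of 100, in at least 11 arrays, while the lowest 12th highest value is 5.82, so the table had been filtered before deposition and weakly expressed genes cannot be examined. Values ran from 2.40 to 14.52 and array medians from 8.32 to 8.56, no 2 arrays were identical, and the highest correlation between 2 arrays was 0.988. The number of arrays limits the precision. Gene symbols came from the human symbols the authors paired with 11602 probe sets, for 8390 different symbols, after 28 symbols that had turned into calendar dates were set aside. The platform annotation gives a symbol for 7333 probe sets, several for 147 of them. For 6611 probe sets with a symbol from both sources, 86.3% were equal ignoring case, and a differing platform symbol is given where such a gene is named. No genome positions come with the series, so none are printed.

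The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The 30% of probe sets with the lowest mean over all arrays were left out, leaving 10029 tested probe sets. Obese and lean pigs were compared within each tissue by limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, two-sided moderated test, Benjamini-Hochberg adjustment over all tested probe sets), and a probe set passed at an adjusted p under 0.05. All 6 groups in 1 limma fit gave the differences of the diet effect between tissues and the comparisons LAD versus TA and PVAT versus LAD, the latter as the mean of the lean and the obese difference. Values are log2 differences with their standard error (SE), and group levels are mean and standard deviation (SD). The table holds no detection calls, so no fold is given where the mean of a compared group lies below 6.64, and the log2 differences there are those of the deposited values.

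Of 34 fixed gene lists, 27 had at least 5 measured members and were tested on 6694 genes, each represented by its probe set with the highest mean over all arrays. The number of measured members was 22 for cholesterol synthesis and uptake, 12 for LXR targets and efflux, 16 for fatty acid and triglyceride synthesis, 22 for fatty acid oxidation, 35 for oxidative phosphorylation (OXPHOS), 9 for adipocyte, 14 for macrophage, 9 for NF-kB inflammation, 17 for interferon response, 27 for contractile smooth muscle, 42 for extracellular matrix, 20 for endothelial, 18 for vasoactive, 21 for oxidative stress and NRF2, 19 for endoplasmic reticulum (ER) stress, 16 for heat shock, 17 for immediate early, 10 for circadian, 12 for glucocorticoid response, 19 for insulin and glucose handling, 22 for hypoxia and glycolysis, 16 for complement and coagulation, 10 for cell cycle, 17 for cardiomyocyte, 9 for neural and Schwann cell, 5 for lymphatic and 14 for positional factor genes. The lists not tested had 3 (thermogenic), 0 (T and NK cell), 0 (B and plasma cell), 3 (skeletal muscle), 2 (erythrocyte), 4 (mesothelial) and 0 (sex-linked) measured members. Each list was tested with camera of limma, two-sided, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated correlation, adjusted by Benjamini-Hochberg over the 27 lists. Members were also counted after adjustment over the list alone. In addition the list mean per array was compared by a two-sided exact permutation test of the diet labels, over 462 splits for LAD and PVAT, 252 for TA and 126 for TA without 1 array. List means of a difference between tissues are over the pigs with both tissues, so pig 63 is left out where TA takes part. The smallest exact p these allow is 0.00216 for 5 against 6 pigs and 0.00794 for the TA comparisons. After adjustment over 27 lists a pass takes at least 2 lists at that p in the former and 5 in the latter, so not passing says little about a single list.

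Named genes follow 3 rules. The first takes up to 10 genes with the largest higher and 10 with the largest lower difference among those that passed, filled up to 5 per direction by the smallest p where fewer passed. The second takes up to 4 members of each list with the smallest p. The last takes 12 fixed genes, among which ADIPOQ, CCL2, NOS3, EDN1 and SCD were measured and LEP, IL6, TNF, PPARGC1A and UCP1 were not. Not every gene these rules select is named in the text. CXCL14, UBE2E3, the plotted genes and the genes shown for 1 odd array were chosen after their values were seen.

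Alternatives covered all 6 groups in 1 fit, the pig as a replicate block (statmod 1.5.0) or as a fixed term, the sacrifice date as a block (3 dates), the 28S/18S ratio of the RNA as a covariate, only arrays with a ratio of at least 0.8, thresholds of 0.1, no filter or the lowest 50% left out, array weights, other normalizations, 1 probe set per gene, and leaving out each pig. Added after the data were seen were fits without the obese TA array of pig 57, the cardiomyocyte list mean as a covariate, the platform's symbols, the exact test of list means and, for the macrophage list, only ratios of at least 0.8 without that array. The tissues of a pig were checked as pairs. After removing group means, the median correlation was 0.261 between LAD and PVAT, 0.324 between LAD and TA and 0.095 between PVAT and TA. The correlation was over 0.1 in 7 of 11, 9 of 10 and 4 of 10 pigs, in that order. The consensus correlation within a pig was 0.0763. By plan the pig was not a term of the reported fits, and its block is an alternative. The reported differences between tissues thus leave out this pairing. Each obese versus lean count was also compared with 100 splits of the samples, the real one included (seed 101).

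The code was tested on simulated data of 10029 probe sets with 100 changed probe sets per size. A log2 change of 1 was recovered for 90% in LAD, 82% in PVAT, 96% in TA, 80% for the difference LAD minus TA and 97% for LAD versus TA. The share of false calls was 5%, 4.28%, 6.67%, 7.25% and 5.31%. A list shifted by 0.5 was recovered in all 3 diet comparisons, with 0 other lists passing. The simulated probe sets varied independently, with the SD of the lean arrays in both diets, so these shares hold only for such data. In the real arrays, other splits of the pigs gave a median of 9 passing lists in LAD, 8 in PVAT and 10 in TA by camera with its preset correlation.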

Results

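The data are log2 expression values of 10029 tested probe sets in the coronary artery, its perivascular fat and the thoracic aorta of 6 lean and 5 obese juvenile pigs. The first 3 principal components held 44.9%, 15.1% and 10.9% of the variance. RNA quality, as the 28S/18S ratio, averaged 1.305 ± 0.117 (SD, n = 6) in lean and 1.094 ± 0.404 (n = 5) in obese LAD. It averaged 1.025 ± 0.144 (n = 6) and 0.878 ± 0.210 (n = 5) in lean and obese PVAT, and 1.378 ± 0.147 (n = 5) and 1.178 ± 0.640 (n = 5) in lean and obese TA. In each tissue 2 obese arrays had a ratio below 0.8. Heart muscle genes varied widely between single LAD and PVAT samples. The mean log2 signal of the cardiomyocyte genes ran from 7.61 to 12.64 in lean LAD, 7.26 to 11.97 in obese LAD. It ran from 6.58 to 12.69 in lean PVAT and 9.18 to 12.85 in obese PVAT, but only from 6.11 to 7.28 in TA. The obese TA array of pig 57 stood apart, with 817 probe sets over 2 log2 units from the other TA arrays. TA values are over all arrays unless said to be without it.

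The comparison of obese with lean pigs in the LAD asks which genes differ with juvenile obesity in a coronary artery. In the LAD, 4 probe sets were higher in obese pigs and 0 were lower, each with a limma adjusted p of 0.0482. SMPDL3A, an acid sphingomyelinase-like phosphodiesterase and known LXR target, rose from 6.79 ± 0.64 (SD, n = 6) to 10.95 ± 1.44 (n = 5), a log2 difference of 4.15 (SE 0.57) or 17.8-fold. SPP1, which encodes osteopontin, rose from 10.33 ± 0.26 to 12.63 ± 0.87, by 2.30 (SE 0.33) or 4.91-fold. C1QA, a chain of complement C1q made mainly by macrophages, rose from 8.16 ± 0.25 to 9.77 ± 0.53, by 1.61 (SE 0.22) or 3.04-fold. CXCL14, a chemokine, rose by 2.88 (SE 0.42) or 7.37-fold on 1 probe set. Its more strongly expressed probe set differed by 2.26 (SE 0.40) with an adjusted p of 0.069. All 5 obese pigs lay above the highest lean pig for SMPDL3A, SPP1 and C1QA. Within the 3 sacrifice dates, the difference ranged from 3.06 to 5.47 for SMPDL3A, from 1.64 to 2.99 for SPP1 and from 1.43 to 2.30 for C1QA. The call was lost in 13 of 25 alternatives for SMPDL3A and in 14 of 26 for SPP1 and C1QA each.

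**Figure D1:**
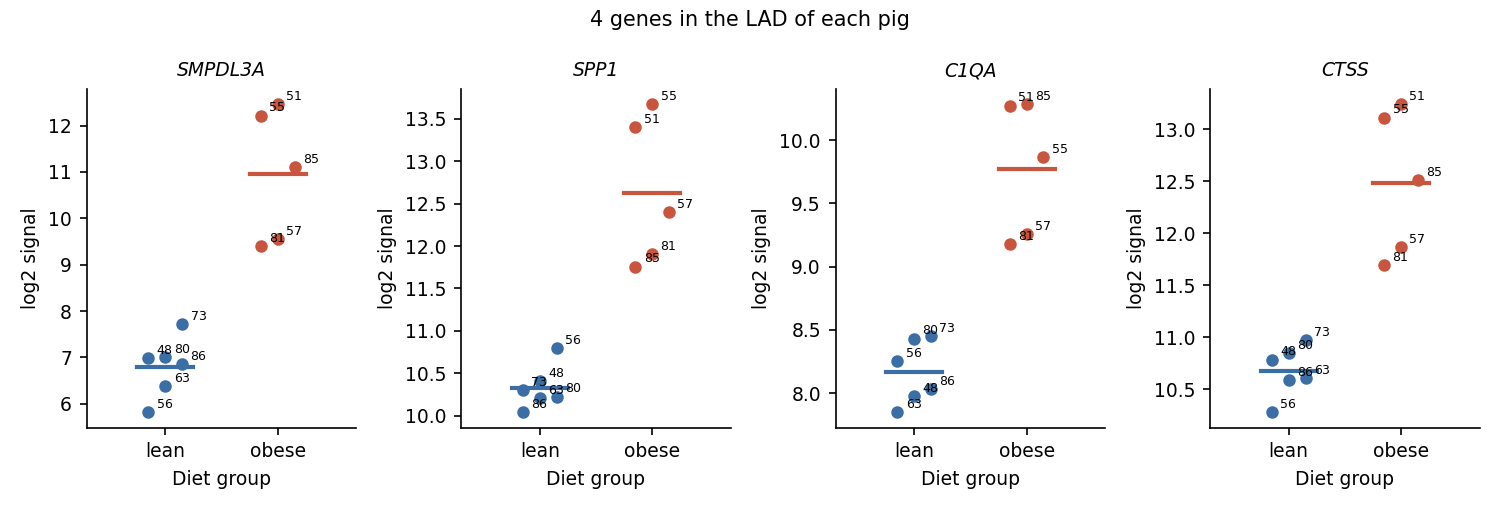
log2 signal of SMPDL3A, SPP1, C1QA and CTSS in the LAD of each pig, with the pig number beside each point and a line at the group mean. All 5 obese pigs lie above the highest of the 6 lean pigs for each gene.

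Macrophage genes were higher in the obese LAD. Of 14 measured members, 12 rose when adjusted over the list alone and 2 (SPP1 and C1QA) over all genes. The list mean rose by 1.47 log2 units, with all 5 obese pigs above the highest lean pig (two-sided exact permutation p = 0.00216, the smallest these groups allow, adjusted p = 0.0195). CTSS, the lysosomal protease cathepsin S, rose by 1.80 (SE 0.27) or 3.49-fold when adjusted over the list alone, with an adjusted p of 0.0508 over all genes. C1QB, another C1q chain, rose by 1.57. The camera test of this list gave an adjusted p of 5.58e-19, and an adjusted p = 0.125 with an estimated correlation. The list mean differed by 1.60, 2.26 and 1.03 within the 3 sacrifice dates. Interferon response genes also rose. All 17 members had a positive difference, and 16 rose when adjusted over the list alone and 0 over all genes. The list mean rose by 0.76, and by 0.64 to 0.87 within dates (exact permutation adjusted p = 0.0195). Camera gave an adjusted p of 1.80e-21, and an adjusted p = 0.125 with an estimated correlation. ISG15, a ubiquitin-like modifier, rose by 1.34, the RNA sensor OAS1 by 1.51, IFIT1 by 0.82 and IFIT3 by 1.21, each adjusted over the list alone.

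Genes of cholesterol handling moved in opposite directions in the obese LAD. Of 22 cholesterol synthesis and uptake genes, 16 fell when adjusted over the list alone and 0 over all genes. The list mean fell by 0.60 (exact permutation adjusted p = 0.0487), with differences of -1.05 to -0.28 within dates. The camera adjusted p was 2.82e-09, and an adjusted p = 0.263 with an estimated correlation. PMVK, a kinase of the mevalonate pathway, fell by 0.70 (SE 0.11) and was lower in all 5 obese pigs than in any lean pig. SC5D, a late sterol desaturase, fell by 1.12 (SE 0.23), and the sterol enzymes CYP51A1 and MSMO1 fell by 0.94 and 0.61, each adjusted over the list alone. Of 12 LXR target genes, 5 rose when adjusted over the list alone and 0 over all genes. The list mean rose by 0.55, and by 0.28 to 0.90 within dates (exact permutation adjusted p = 0.0195). By camera the adjusted p was 1.51e-06, and an adjusted p = 0.197 with an estimated correlation. APOE, the lipid carrier apolipoprotein E, rose by 2.73 or 6.66-fold, the cholesterol exporter ABCA1 by 1.39 or 2.62-fold. PLTP (ICAM1 in the platform annotation) rose by 0.63, and NR1H3, the receptor LXR alpha itself, by 0.62.

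**Figure D2:**
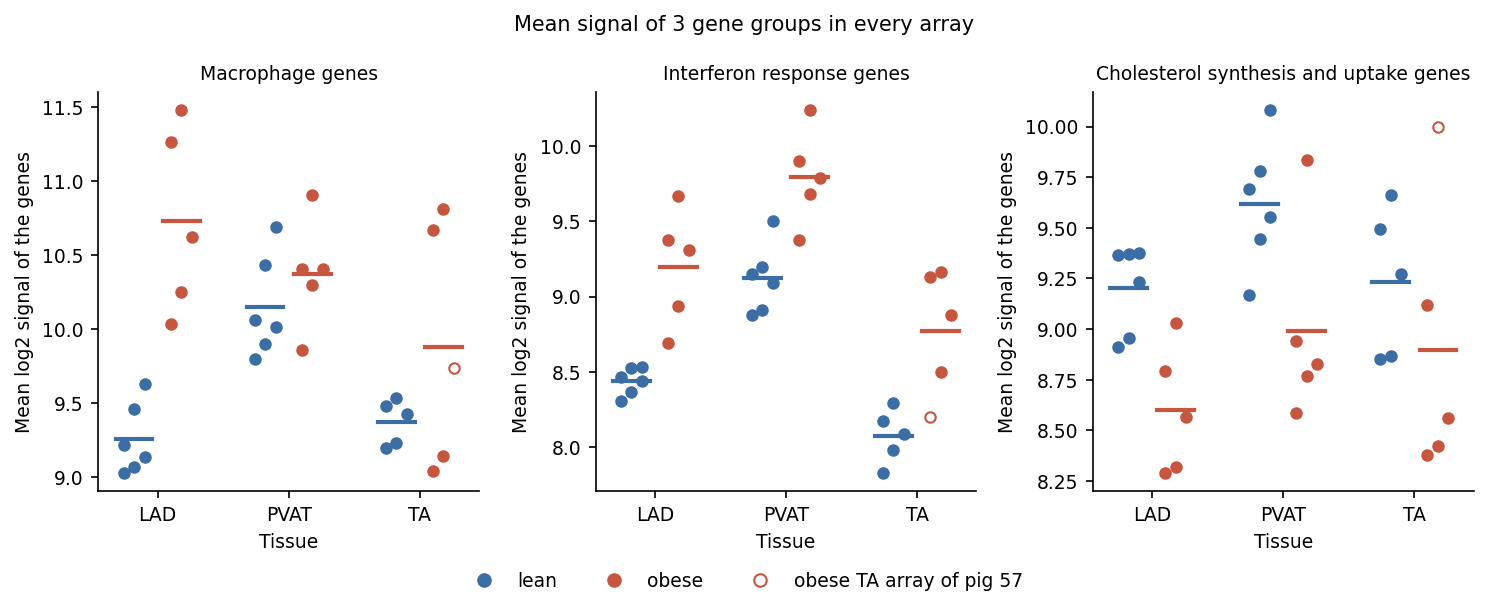
Mean log2 signal of the macrophage, interferon response, and cholesterol synthesis and uptake genes in every array by tissue and diet, with a line at the group mean and the obese TA array of pig 57 as an open circle. The macrophage and interferon means of all 5 obese LAD arrays lie above the highest lean LAD array.

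Smaller groups of LAD genes passed as well, adjusted over the list alone and with 0 of their members passing over all genes. In the NF-kB list 5 of 9 members rose when adjusted over the list alone. Among them were CCL2, the monocyte chemoattractant, by 0.82, the endotoxin receptor TLR4 by 1.38, TNFRSF1B by 0.39 and the adhesion molecule VCAM1 by 0.55 (list camera adjusted p = 0.00165, and adjusted p = 0.325 with an estimated correlation). CPT1A, the carnitine shuttle enzyme of fatty acid oxidation, rose by 0.75 (SE 0.11) and the lipase inhibitor ANGPTL4 by 0.82. They were the 2 of 22 fatty acid oxidation genes that passed over the list alone (camera adjusted p = 0.00475, and adjusted p = 0.64 with an estimated correlation). In the oxidative stress list 1 of 21 rose, CYBB, the catalytic subunit of the phagocyte NADPH oxidase, by 1.99 or 3.98-fold. That list's mean differed by 0.28 (camera adjusted p = 1.39e-05, and adjusted p = 0.308 with an estimated correlation). In the extracellular matrix list 1 of 42 rose, POSTN, the matricellular protein periostin, by 1.63 or 3.1-fold. In the vasoactive list DDAH1, which breaks down an inhibitor of nitric oxide synthesis, rose by 0.68 and the angiotensin receptor AGTR1 fell by 0.67, out of 18. The clock genes CRY2 and HLF fell by 0.51 and 0.73, the 2 of 10 circadian genes that passed. HOXA10 rose by 0.34 and GATA4 fell by 0.42 among 14 positional factors, and ANGPTL4 was also the 1 of 12 glucocorticoid response genes that rose. Of 27 contractile smooth muscle genes 25 had a negative difference and 0 passed over the list alone. SYNM (SYNM and MYOZ2 in the platform annotation) was at -0.52 and PGM5 at -0.49. The list mean fell by 0.20 (exact permutation adjusted p = 0.0468, camera adjusted p = 4.89e-04, and adjusted p = 0.539 with an estimated correlation). The mean of the complement and coagulation genes rose by 0.15 with 0 of 16 members passing (exact permutation adjusted p = 0.0468, camera adjusted p = 0.00796, and adjusted p = 0.197 with an estimated correlation).

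Endothelial (0.21, 0 of 20 members), ER stress (0.06, 0 of 19), immediate early (0.16, 0 of 17), cell cycle (0.31, 0 of 10) and cardiomyocyte genes (0.79, 0 of 17) passed camera upward. Their adjusted p values with an estimated correlation were 0.329, 0.64, 0.64, 0.633 and 0.712, in that order. Within dates, the difference ran from 0.09 to 0.30 for the endothelial and from -0.16 to 2.42 for the cardiomyocyte genes. It ran from -0.04 to 0.15 for the ER stress, -0.41 to 0.64 for the immediate early and -0.34 to 0.66 for the cell cycle genes. No member passed among the fatty acid and triglyceride synthesis (list mean 0.03), OXPHOS (-0.02), adipocyte (0.05), insulin and glucose (-0.01), hypoxia (-0.02), heat shock (-0.02), neural and Schwann cell (-0.10) and lymphatic genes (0.02), and these lists did not pass. The median, mean and test differed in sign for all of them except the synthesis and lymphatic lists, as they did for the matrix list (mean 0.02). Of the fixed genes, SCD differed by 0.84, EDN1 by 0.36, NOS3 by 0.12 and ADIPOQ by 0.16, and none passed over all genes. At an unadjusted p under 0.05 there were 1720 probe sets, 551 higher and 1169 lower, where 501 are expected by chance. In all, 21 had an adjusted p under 0.1. The count depended on single pigs, with 102 probe sets passing without pig 57, 106 without pig 81, 1 without pig 56 and 0 without any other pig. With the 28S/18S ratio or the cardiomyocyte mean as a covariate 0 passed, and with all 6 groups in 1 fit and the pig as a block 90 passed.

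The comparison in PVAT asks for the same diet difference in the fat that lies against the coronary artery. The mean of the interferon genes was higher and the means of cholesterol and fatty acid synthesis genes were lower in obese PVAT. Over all genes 0 probe sets passed (limma, smallest adjusted p 0.64). At an unadjusted p under 0.05 there were 221, fewer than the 501 expected by chance. Of 17 interferon response genes all had a positive difference and 15 rose when adjusted over the list alone, 0 over all genes. RSAD2, the antiviral protein viperin, rose from 8.01 ± 0.67 (SD, n = 6) to 9.84 ± 0.73 (n = 5), by 1.84 (SE 0.38) or 3.57-fold. ISG15 rose by 1.21, the RNA helicase DDX58 by 0.87 and IFIT1 by 0.80, each adjusted over the list alone. The list mean differed by 0.68, and by 0.39 to 0.93 within dates, with 4 of 5 obese pigs above the highest lean pig. The list passed camera with an adjusted p of 1.22e-34, and with an adjusted p = 0.0419 with an estimated correlation. It did not pass the exact permutation test after adjustment (p = 0.00649, adjusted p = 0.175). SAMD9, an antiviral factor by the deposited symbol and an unnamed locus in the platform annotation, was 0.81 (SE 0.14) and HERC6, an interferon-induced ligase, 0.78 higher without passing over all genes. INHBB, an activin subunit, was 0.87 (SE 0.18) higher, also without passing.

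All 22 cholesterol synthesis and uptake genes had a negative difference in PVAT, and 10 fell when adjusted over the list alone, 0 over all genes. INSIG1, the sterol-sensing brake on SREBP processing and itself an SREBP target, fell by 1.16 (SE 0.22) or 2.23-fold. PMVK fell from 8.34 ± 0.26 to 7.65 ± 0.14, by 0.69 (SE 0.13). LSS and EBP, enzymes of sterol synthesis, fell by 1.03 and 0.72, each adjusted over the list alone. The list mean differed by -0.63, and by -0.92 to -0.26 within dates (exact permutation p = 0.0346, adjusted p = 0.448). In the obese array of pig 81 it was 9.84, within the lean range of 9.17 to 10.08. The other obese arrays ran from 8.59 to 8.94. Camera gave an adjusted p of 3.39e-30, and an adjusted p = 0.107 with an estimated correlation. Of 16 fatty acid and triglyceride synthesis genes 5 fell when adjusted over the list alone. FASN, fatty acid synthase, fell from 12.16 ± 0.67 to 10.14 ± 1.05, by 2.02 (SE 0.46) or 4.05-fold. ME1, the malic enzyme that supplies NADPH, fell by 1.87 (SE 0.44) or 3.65-fold, SCD, the stearoyl-CoA desaturase, by 1.59 and ACLY, ATP citrate lyase, by 1.20, each adjusted over the list alone. The list mean differed by -0.84, and by -1.33 to -0.23 within dates (exact permutation p = 0.0498, adjusted p = 0.448). The camera adjusted p was 5.25e-13, and an adjusted p = 0.201 with an estimated correlation. Among 12 LXR targets PLTP (ICAM1 in the platform annotation) rose by 0.32 and ABCA1 by 0.78 while SCARB1, the HDL receptor, fell by 0.39, adjusted over the list alone. The list itself did not pass (mean 0.07, camera adjusted p = 0.0763).

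Other PVAT lists passed camera with its preset correlation while 0 of their members passed. Mean differences were 0.22 for 14 macrophage, 0.16 for 20 endothelial, -0.13 for 35 OXPHOS and -0.15 for 27 contractile smooth muscle genes (adjusted p = 0.741, 0.451, 0.772 and 0.741 with an estimated correlation). They were -0.10 for 42 matrix, -0.10 for 10 circadian and -0.21 for 9 neural and Schwann cell genes (adjusted p = 0.741, 0.338 and 0.741 with an estimated correlation). Adipocyte genes differed by -0.13 with 0 of 9 passing, and ADIPOQ, adiponectin, had the same level of 10.85 ± 0.11 in both groups. Cardiomyocyte genes differed by 0.43 with 0 of 17 passing, and by -2.36 to 2.48 within dates. The lean array of pig 73 had a cardiomyocyte mean of 6.58, against 10.31 to 12.69 in the other lean PVAT arrays. The remaining lists had 0 members passing and did not pass. For the oxidative stress and heat shock lists the median, mean and test differed in sign. CPT1A and ANGPTL4 differed by 0.84 and 1.30, CCL2 by 0.31, EDN1 by 0.10 and NOS3 by 0.04, with its other probe set at -0.02, and none passed. With all 6 groups in 1 fit, 2 probe sets passed with or without the pig as a block, and 1 passed without pig 56.

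The comparison in TA asks for the diet difference in a large conduit artery. Over all arrays 0 probe sets passed (limma, smallest adjusted p 0.143), with 720 at an unadjusted p under 0.05, 367 higher and 353 lower. Without the obese TA array of pig 57, leaving 4 obese and 5 lean arrays, 29 passed, 26 higher and 3 lower, with 1069 at an unadjusted p under 0.05. In that fit RSAD2 rose from 6.13 ± 0.30 (SD, n = 5) to 8.40 ± 0.61 (n = 4), by 2.27 (SE 0.27) with an adjusted p of 0.0171. ALDH1A2, which makes retinoic acid, rose 2.57-fold, SRGN, a granule proteoglycan, 2.38-fold, ABCA1 2.29-fold and TSPAN12, a tetraspanin of endothelial Wnt signalling, 2.26-fold. The adhesion molecule VCAM1 rose by 0.91, the endothelial diaphragm protein PLVAP by 1.01, the growth factor binding protein IGFBP2 by 0.91 and C17orf72 (ICAM2, an endothelial adhesion molecule, in the platform annotation) by 1.04 (SE 0.09). The lower probe sets were 2 of UBE2E3, a ubiquitin-conjugating enzyme, at -0.51 and -0.63, and 1 without a symbol. Leaving out 1 more pig gave 31 probe sets without pig 81, 19 without 48, 13 without 56, 6 without 55, 3 without 73, 2 without 51, and 1 each without 80, 85 and 86.

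Interferon genes were higher in the obese TA. All 17 members had a positive difference with every array included and 8 rose when adjusted over the list alone, 0 over all genes. RSAD2 rose by 2.06 (SE 0.32), the immunoproteasome subunits PSMB8 and PSMB9 by 0.86 and 0.77, and ISG15 by 1.37. The list mean differed by 0.70, and by 0.61 to 0.85 within dates (exact permutation p = 0.0159, adjusted p = 0.429). By camera the adjusted p was 5.83e-13, and an adjusted p = 0.589 with an estimated correlation. Without array 57, 13 of 17 rose, OAS1 by 1.65 and IFIT1 by 1.00 among them (adjusted p = 0.229 with an estimated correlation). Endothelial genes were also higher, with 7 of 20 rising over the list alone and 13 without array 57. The angiopoietin receptor TEK rose by 1.22 with and 1.46 without that array, the junction protein PECAM1 by 0.95 and 1.05, and PLVAP by 0.93 and 1.01. VWF, von Willebrand factor, rose by 1.09 in the full set. The endothelial list mean differed by 0.53 and 0.70, and by -0.05 to 0.99 within dates without array 57. It was highest in the obese arrays of pigs 81 and 85 (9.16 and 9.44), whose 28S/18S ratios were 0.61 and 0.57. In the obese array of pig 55 it was 8.75. In those of pigs 51 and 57 it was 8.42 and 8.12, within the lean range of 7.81 to 8.54. For this list the camera adjusted p was 2.39e-08 in the full set, and adjusted p = 0.664 and, without array 57, 0.271 with an estimated correlation.

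Cholesterol synthesis and uptake genes had a mean difference of -0.34 with 0 of 22 passing over all TA arrays (adjusted p = 0.756 with an estimated correlation). Without array 57 it was -0.61, with 7 falling over the list alone, SQLE, squalene epoxidase, by 1.61 or 3.05-fold (adjusted p = 0.357 with an estimated correlation). LXR targets differed by 0.17 and, without array 57, by 0.33 (adjusted p = 0.664, and 0.266 without array 57, with an estimated correlation). Of 12 members 2 rose, ABCA1 by 1.04 and PLTP (ICAM1 in the platform annotation) by 0.79. Without that array they rose by 1.19 and 0.93. CPT1A and ANGPTL4 each rose by 0.75 over the list alone (0.65 and 0.70 without array 57), 2 of 22 fatty acid oxidation genes. ANGPTL4 was also the 1 of 12 glucocorticoid response genes to rise, of which 0 passed without array 57. VCAM1 rose by 0.76, 1 of 9 NF-kB genes, and the matrix protein THBS1 by 1.51, and 1.52 without array 57, 1 of 42 matrix genes. The binding proteins IGFBP2 and IGFBP3 rose by 1.07 and 0.85 (0.91 and 0.80 without it), 2 of 19 insulin genes. Over all TA arrays each of these genes passed over its list alone and none over all genes. Without array 57 IGFBP2, VCAM1 and ABCA1 passed over all genes (limma adjusted p = 0.0397, 0.0312 and 0.0312). Macrophage genes differed by 0.51 with 0 of 14 passing (adjusted p = 0.714 with an estimated correlation). Without array 57 their mean differed by 1.14 and 1.33 in the 2 dates with 1 obese and 1 lean array. It differed by -0.19 in the date with 3 lean arrays and the obese arrays of pigs 81 and 85, whose 28S/18S ratios were 0.61 and 0.57. Contractile smooth muscle genes differed by -0.36 and, without array 57, by -0.15 with 0 of 27 passing, and matrix genes by -0.30 and, without it, 0.13. The other lists, with 0 members passing over all TA arrays, had mean differences of 0.22 (oxidative stress), 0.17 (ER stress), 0.19 (hypoxia), 0.10 (complement), -0.24 (circadian) and -0.27 (cardiomyocyte). In the same order they were 0.10, 0.03, 0.10, 0.19, -0.10 and -0.09 without array 57. They were 0.31 (cell cycle), 0.13 (fatty acid and triglyceride synthesis), 0.05 (OXPHOS), -0.18 (vasoactive) and -0.01 (neural), and without that array 0.00, -0.07, -0.09, 0.05 and 0.40, so 4 of these 11 changed sign. No member passed among the lymphatic, positional, heat shock, immediate early and adipocyte genes. The median, mean and test differed in sign for the adipocyte, glucocorticoid, neural and positional lists. SCD differed by 0.35, EDN1 by 0.67, NOS3 by 0.72 with its other probe set at -0.11, CCL2 by -0.26 and ADIPOQ by -0.10. Without array 57 they were at 0.06, 0.87, 1.07, 0.05 and 0.10, and none passed over all genes either way. With the 28S/18S ratio as a covariate 547 probe sets passed, with array weights 265, and with all 6 groups in 1 fit 60, or 57 with the pig as a block. The ratio of array 57 was 2.14, against at most 1.54 in the other TA arrays, so this covariate is tied to that array. Fewer passed with the covariate when that array was left out, as given further below.

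The title of the series concerns artery-specific changes, which the difference of the diet effect between tissues addresses. No probe set passed for LAD minus TA (limma, smallest adjusted p 0.998), PVAT minus LAD (0.877) or PVAT minus TA (0.608). Thus no single gene was shown to differ in its response in this fit. At an unadjusted p under 0.05 there were 227, 292 and 493, in that order, each below the 501 expected by chance. As a group, macrophage genes had a larger diet difference in LAD than in TA, by 0.93 over the 10 pigs with both tissues, with 8 of 14 higher when adjusted over the list alone, 3 without array 57, and 0 over all genes, C1QA by 1.52, C1QB by 1.66 and C1QC by 1.58. For this list the camera adjusted p was 2.70e-14, and an adjusted p = 0.164 with an estimated correlation (exact permutation p = 0.0159, adjusted p = 0.321). The difference was 0.97 over all arrays and 0.49 with only arrays with a 28S/18S ratio of at least 0.8. It was 0.16 when array 57 was also left out, which leaves 2 obese TA arrays, a value looked up after the result was seen. The diet difference of the same list was smaller in PVAT than in LAD by 1.25, with 10 of 14 lower over the list alone, CTSS at -1.52 among them. This list passed with an estimated correlation (adjusted p = 0.0285), but not without array 57 (0.0632) or by the exact permutation test (p = 0.00433, adjusted p = 0.0877). Fatty acid and triglyceride synthesis genes differed by -0.87 between PVAT and LAD, with 7 of 16 lower over the list alone, FASN at -1.77, SCD at -2.43 and ME1 at -1.69. This list passed too (adjusted p = 0.0388 with an estimated correlation, 0.0632 without array 57, and exact permutation adjusted p = 0.205). Between PVAT and TA the same list differed by -0.999 over the 10 pigs with both, with 4 of 16 lower, 2 without array 57 (adjusted p = 0.392 with an estimated correlation). LXR targets differed by -0.48 between PVAT and LAD, with 2 of 12 lower over the list alone (adjusted p = 0.104 with an estimated correlation, and exact permutation adjusted p = 0.0877). SMPDL3A differed by -3.94 and APOE by -3.17 there without passing over all genes. With the pig as a fixed term, which compares the tissues within each pig, 2 probe sets passed, SMPDL3A among them (limma adjusted p = 0.0206, against 0.0206 to 0.99998 over all alternatives). Within a pig, SMPDL3A in PVAT minus that in LAD ran from 0.72 to 1.92 in the 6 lean and from -3.96 to -1.75 in the 5 obese pigs, values looked up after the result was seen. In TA it was also higher in obese pigs, by 2.995 (SE 0.96, limma adjusted p = 0.582) without passing, and LAD minus TA gave 1.16 (SE 1.03, adjusted p = 0.998). Within dates and without array 57, the TA difference was 5.32, 4.82 and 0.62.

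The comparison of LAD with TA describes how the arteries differ at either diet. In this fit 2458 probe sets passed, 1445 higher in LAD and 1013 lower, for 1755 named genes. Without array 57, 3211 passed, of which 2316 were shared. Member counts in this comparison are adjusted over the list alone, unless said to be over all genes. Heart muscle genes were among the largest differences, with TNNT2, cardiac troponin T, higher in LAD at 5.95 (SE 0.91). The myosin light chains MYL2 at 5.30 and MYL3 (MYH7 in the platform annotation) at 4.93, myoglobin MB at 4.82, titin TTN at 4.54 and cardiac troponin I, TNNI3, at 4.45 were higher as well. Of 17 cardiomyocyte genes 12 were higher and 1 was lower, with the wide spread between single LAD samples given above (adjusted p = 0.863 with an estimated correlation). Genes of nerve and Schwann cells followed, with MBP, a protein of myelin, higher at 4.88 (SE 0.24) on 1 of its 2 probe sets (-0.07 with SE 0.24 on the other, not passing), and the glial filament gene GFAP at 1.93. Of 9 neural genes 8 were higher, 7 over all genes (list mean 2.29, adjusted p = 0.276 with an estimated correlation). The transcription factors GATA4 at 4.38 (SE 0.11) and TCF21 at 4.81 (SE 0.25) were higher in LAD. SFRP2, a secreted Wnt modulator, was lower at -6.14 (SE 0.31) and HOXA3 at -5.04 (SE 0.47). Of 14 positional factors 7 were higher and 5 lower.

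Endothelial genes were higher in LAD for 14 of 20 members and lower for 2, and for 12 and 1 over all genes, ESAM at 1.66, TEK at 1.29 and PECAM1 at 1.13 (adjusted p = 0.863 with an estimated correlation). Complement genes were higher for 8 of 16, 7 over all genes, C7 at 2.60 among them (adjusted p = 0.276 with an estimated correlation). Matrix genes were higher for 10 of 42, THBS1 at 2.71 and TNC at 2.66, and 12 were higher and 11 lower without array 57. Contractile smooth muscle genes were higher for 7 of 27, DES, desmin, at 3.66. They were lower for 3, SYNM (SYNM and MYOZ2 in the platform annotation) at -0.95 and PGM5 at -0.77. Whether heart muscle RNA in the LAD samples raised any of these members was not tested. Insulin genes were higher for 7 of 19 and lower for 2, IGFBP2 at 2.94 (7.69-fold) and IGF1 at 1.27. Vasoactive genes were higher for 6 and lower for 1 of 18, AGT, angiotensinogen, at 1.97 and the natriuretic peptide receptor NPR1 at -1.50. Interferon genes were higher for 8 of 17 (adjusted p = 0.863 with an estimated correlation). Immediate early genes were lower for 6 of 17 and higher for 1, FOS at -1.77 and MYC at -1.14. Hypoxia genes were higher for 5 and lower for 5 of 22, EPAS1 at 1.17 and HIF1A at -0.51, and NF-kB genes higher for 3 and lower for 2 of 9. Adipocyte genes were higher for 2 of 9, LPL at 2.42 and CFD at 1.32, and lymphatic genes higher for 2 and lower for 1 of 5. None passed of 35 OXPHOS, 14 macrophage and 10 cell cycle genes, where over all genes 3 OXPHOS and 2 macrophage genes were higher. Counts higher and lower were 2 and 0 for glucocorticoid, 0 and 2 for circadian, 2 and 4 for heat shock, 2 and 1 for oxidative stress, 2 and 1 for ER stress genes. They were 0 and 1 for cholesterol, 1 and 1 for LXR, 1 and 1 for fatty acid synthesis and 1 and 0 for fatty acid oxidation genes. Of the 27 lists 6 passed camera and 0 with an estimated correlation. The median, mean and test differed in sign for the fatty acid synthesis, heat shock, circadian, insulin and lymphatic lists. With array weights 4139 probe sets passed.

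The comparison of PVAT with LAD describes the fat beside the artery it surrounds, with the RNA kit differing along with the tissue. In it 5677 probe sets passed, 2428 higher in PVAT and 3249 lower, for 3944 named genes. Member counts here are over all genes, with those over the list alone where they differ. Genes of fat were higher in PVAT, among them DGAT2, which completes triglyceride synthesis, at 4.50 (SE 0.49) and CIDEA, a lipid droplet protein, at 4.14 (SE 0.44). CA3, a carbonic anhydrase of fat and muscle, was higher at 5.06 (SE 0.44), and AGT at 3.76 (SE 0.34) or 13.5-fold. Fatty acid and triglyceride synthesis genes were higher for 14 of 16 and adipocyte genes for 6 of 9, FABP4 at 2.69 (6.43-fold) and LPL at 2.71 (list means 1.45 and 1.23, each with an adjusted p = 0.339 with an estimated correlation). Fatty acid oxidation genes were higher for 15 of 22, with 1 lower over the list alone, and OXPHOS genes for 34 of 35 (list means 0.55 and 0.62, adjusted p = 0.458 and 0.468 with an estimated correlation). Cardiomyocyte means were also higher, at 11.01 and 11.44 in lean and obese PVAT against 9.37 and 10.16 in LAD. Over the PVAT arrays the OXPHOS mean followed the cardiomyocyte mean (Pearson r 0.764). Contractile smooth muscle genes were lower for 23 of 27, 24 over the list alone, CNN1, calponin, at -2.60 (adjusted p = 0.339 with an estimated correlation). Matrix genes were lower for 28 and higher for 2 of 42, TNC at -2.34 and BGN, biglycan, at -2.27 (adjusted p = 0.586 with an estimated correlation). The potassium channel gene KCNMA1 of the vasoactive list was lower at -3.00 (SE 0.17). WIF1, a secreted Wnt inhibitor, was 57.3-fold lower at -5.84 (SE 0.53), and A2M, a protease inhibitor, was lower at -3.52.

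Endothelial genes were higher in PVAT for 15 of 20 and lower for 1, with KDR, a VEGF receptor, at 2.28 (4.86-fold). Lymphatic genes were higher for 5 of 5, LYVE1 at 2.61, and neural genes for 7 of 9, STMN2 at 4.99. Interferon genes were higher for 11 of 17, 12 over the list alone, OAS1 at 1.53, cholesterol genes for 11 of 22, HSD17B7 at 1.33, and NF-kB genes for 5 of 9. Macrophage genes were higher for 5 of 14, F13A1 at 1.51 and CD163 at 1.16, and lower for 1, FOLR2 at -0.69. Hypoxia genes were higher for 13 and lower for 5 of 22, VEGFA at 2.10, and oxidative stress genes higher for 9 and lower for 1 of 21, GPX3 at 2.33 (5.05-fold). Cell cycle genes were lower for 6 of 10, ER stress genes for 8 of 19, 7 over the list alone, and circadian genes for 5 of 10, PER2 at -0.83. Counts higher and lower were 6 and 1 for glucocorticoid, 4 and 1 for LXR, 5 and 8 for vasoactive, 6 and 5 for insulin, 6 and 4 for complement, 3 and 3 for heat shock, 2 and 3 for immediate early, 1 and 2 of them over the list alone, and 2 and 5 for positional factor genes. Cardiomyocyte genes were higher for 7 of 17 over all genes and for 2 over the list alone, FABP3, a fatty acid binding protein of heart, at 2.66. Of the 27 lists 14 passed camera and 0 with an estimated correlation. The median, mean and test differed in sign for the heat shock and complement lists.

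**Figure D3:**
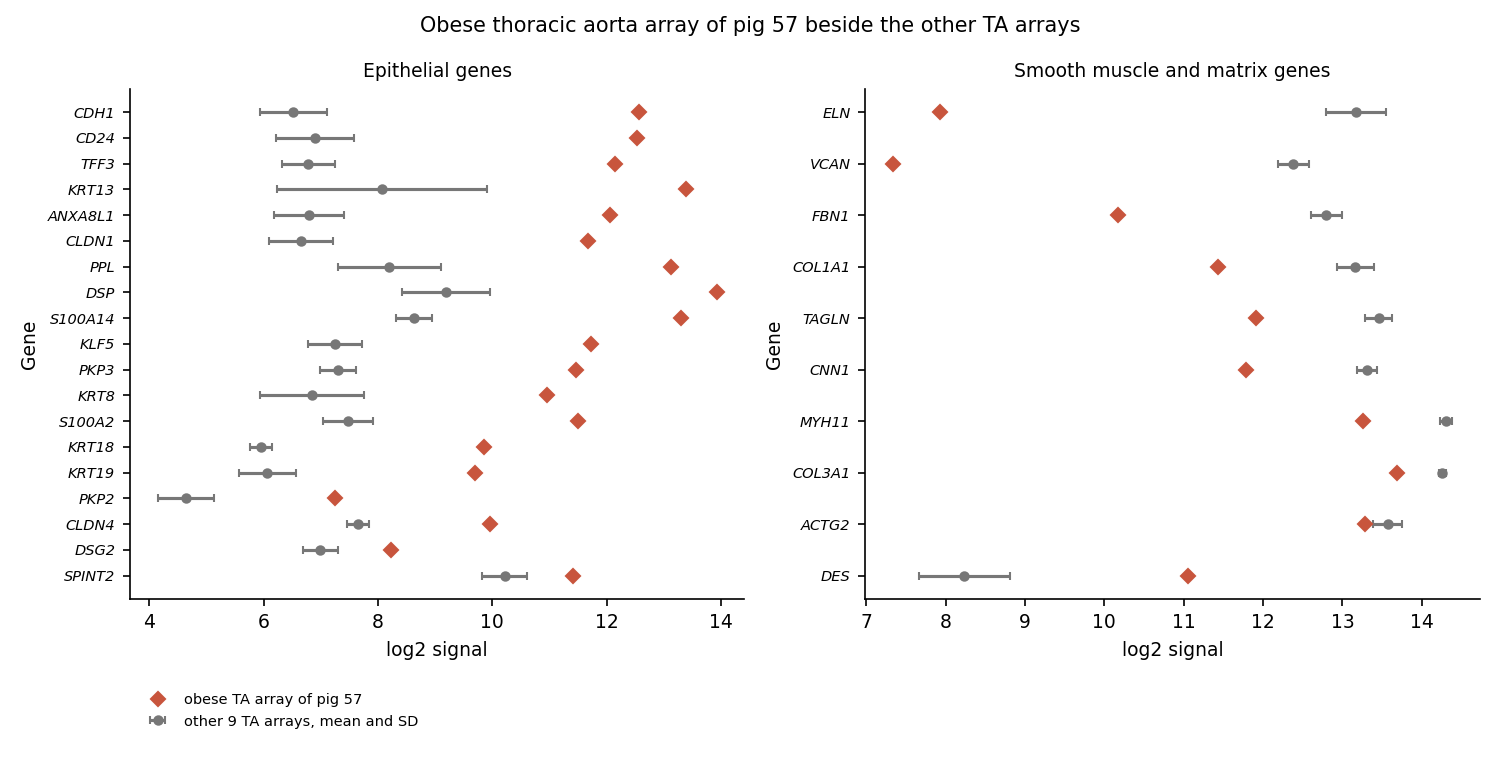
log2 signal of epithelial genes and of smooth muscle and matrix genes in the obese TA array of pig 57 (diamonds) beside the mean and SD of the other 9 TA arrays (circles with bars). ELN, elastin, is at 7.93 in that array against 13.17 ± 0.38, and CDH1, E-cadherin, at 12.57 against 6.52 ± 0.58.

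**Figure D4:**
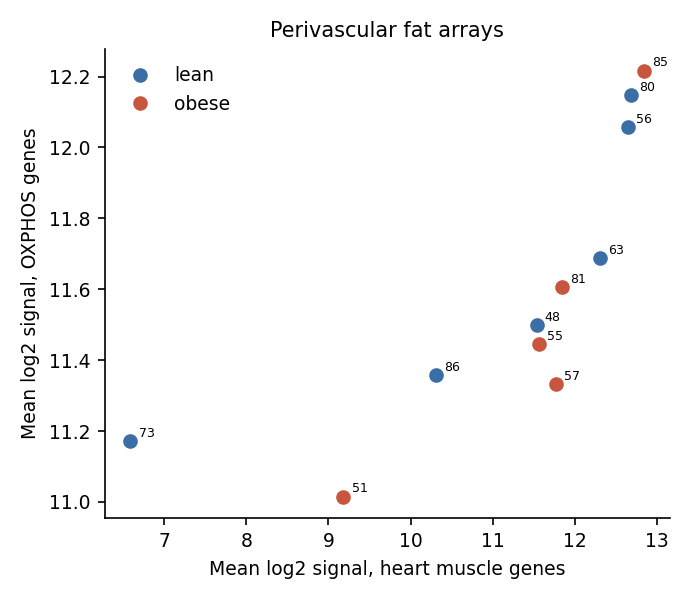
Mean log2 signal of the OXPHOS genes against that of the cardiomyocyte genes in the 11 PVAT arrays, 6 lean and 5 obese, with pig numbers beside the points. Arrays with a higher cardiomyocyte mean have a higher OXPHOS mean, with a Pearson correlation of 0.764.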

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

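The fits without 1 array, the covariate of heart muscle genes, the exact tests of lists, the tests of RNA quality, carry-over and sacrifice date for the macrophage genes, the RNA ratio of array 57 and the correlation of PVAT genes with heart muscle genes were tests chosen only after the result was seen. In all, 186 checks were made, each of 1 measure within 1 of the 6 groups of samples. In 14 of them an array had a list mean that stood apart from the rest of its group. Chance does so in about 1 in 20 checks, or 9.3, if the checks are independent. They reuse the same arrays and so are not, and 6 of the 14 are the obese TA array of pig 57. In 24 cases the diet difference of a gene list differed between tissues by camera with its preset correlation.

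The first pattern weighed is the macrophage list, which rose by 1.47 in the obese LAD. Obese LAD arrays of low RNA quality do not account for it, since the difference was 1.53 (SE 0.377) with only the 3 obese arrays with a 28S/18S ratio of at least 0.8. Fat or heart muscle carried over into the LAD samples does not account for it either, since the difference was 1.54 (SE 0.320) with the means of both kinds of marker genes as covariates. The sacrifice date does not, since the difference was at least 1.03 within each date, with 1.60 and 2.26 in the other dates. A candidate explanation that stays open, as a hypothesis found and tested on the same data, is a diet effect on the number or the state of macrophages in the coronary wall, and which of these was not tested.

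The second pattern is the obese TA array of pig 57, which had 817 probe sets over 2 log2 units from the other TA arrays against 1 to 20 in those, and a correlation with their mean of 0.690 against at least 0.965. All 19 measured epithelial markers were over 1 log2 unit higher in it (median 4.48), among them DSP at 13.92, KRT13 at 13.39 and CDH1 at 12.57, while the aortic matrix genes ELN at 7.93 and VCAN at 7.34 lay far below their levels of 13.17 and 12.38, although MYH11 was still at 13.25. Epithelial tissue in the sample may explain this: 6 epithelial markers not among the genes first seen had a median 2.46 higher in the array, against at most 0.238 in any other TA array, though the other TA arrays also carry signal for these markers, from a mean of 4.64 for PKP2 to 10.22 for SPINT2. The tables argue against a swap with another array of the series, because 0 of the 22 LAD and PVAT arrays correlated best with the TA mean, and against low RNA quality, because its 28S/18S ratio was 2.14 against a median of 1.29 in the other TA arrays. No biological explanation was tested, and a sample of another tissue from outside the series stays open.

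The third pattern is the OXPHOS genes, whose mean varied between PVAT arrays. It followed the mean of the cardiomyocyte genes over the 11 PVAT arrays, with a Pearson r of 0.764 (permutation p = 0.0034) and a Spearman rho of 0.927 (permutation p = 1.70e-04), a Benjamini-Hochberg adjusted p of 0.014 over 4 relations, and r of 0.846 without the 2 arrays farthest from the median. Heart muscle RNA in the fat samples is a candidate explanation of the spread, and a difference in mitochondrial content of the fat itself stays open. The mean of the fatty acid oxidation genes gave r of 0.529 (permutation p = 0.1), adipocyte genes -0.507 (p = 0.1) and macrophage genes -0.189 (p = 0.59), with adjusted p values of 0.13, 0.13 and 0.59.

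The other arrays that stood apart are given as values. Fatty acid oxidation genes in the lean LAD array of pig 63 had a mean of 9.97, against 9.21 to 9.30 in the other lean LAD arrays, and OXPHOS genes 11.75 against 10.79 to 10.85. Its cardiomyocyte mean was 12.64 against 7.61 to 10.27 in those arrays, and a link was not tested. Cholesterol genes in the obese PVAT array of pig 81 had a mean of 9.84 against 8.59 to 8.94, and endothelial genes in that of pig 51 had 10.19 against 9.87 to 9.93. Insulin genes in the obese LAD array of pig 55 had 10.09 against 9.88 to 9.92, and hypoxia genes in the lean PVAT array of pig 73 had 10.50 against 10.68 to 10.76. In the lean TA array of pig 56 neural genes had 7.51 against 7.81 to 7.88 and positional factors 8.38 against 8.80 to 8.88. In the obese TA array of pig 57 fatty acid oxidation genes had 9.79 against 9.25 to 9.36, smooth muscle genes 10.85 against 11.72 to 12.07 and matrix genes 9.89 against 11.97 to 12.14. In the same array vasoactive genes had 8.56 against 9.63 to 9.84, cardiomyocyte genes 6.11 against 6.84 to 7.07 and neural genes 6.12 against 7.89 to 8.48.

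Differences with TA in this paragraph are over the 10 pigs with both tissues, so without pig 63. The diet difference in LAD minus that in TA was 0.93 for the macrophage, 0.38 for the LXR, 0.13 for the smooth muscle, 0.28 for the matrix, 0.46 for the immediate early and 1.72 for the cardiomyocyte list. It was -0.33 for the cholesterol, -0.24 for the endothelial and -0.17 for the hypoxia list. Over all arrays it was 1.06 for the cardiomyocyte, 0.32 for the immediate early, -0.27 for the cholesterol, -0.32 for the endothelial and -0.21 for the hypoxia list. For the macrophage list it was 0.97 over all arrays, 0.49 with only arrays with a 28S/18S ratio of at least 0.8, and 0.16 when array 57 was also left out, which leaves 2 obese TA arrays. Over the pigs other than pig 57, LAD minus TA was -0.10 for the smooth muscle, -0.08 for the matrix, -0.04 for the cholesterol and -0.09 for the hypoxia list, and 0.28 for the LXR list, none of which passed camera without array 57. PVAT minus LAD gave -1.25 for the macrophage, -0.87 for the fatty acid and triglyceride synthesis, -0.48 for the LXR and -0.31 for the NF-kB list. It gave -0.28 for the cell cycle, -0.25 for the oxidative stress, -0.12 for the matrix and -0.11 for the OXPHOS list. PVAT minus TA gave -0.999 for the fatty acid and triglyceride synthesis, -0.42 for the endothelial, -0.28 for the cholesterol and -0.22 for the oxidative stress list, and -0.18 for the hypoxia, -0.17 for the OXPHOS and -0.14 for the ER stress list. Leaving pig 57 out here too, the cholesterol list was at 0.04, the oxidative stress list at -0.09, and the OXPHOS and ER stress lists each at 0.01, and none of these passed camera without that array. With an estimated correlation, 2 of these 24 hold, macrophage (adjusted p = 0.0285) and fatty acid and triglyceride synthesis (adjusted p = 0.0388) for PVAT minus LAD, both at 0.0632 without array 57, and the exact permutation test, which no list passes after adjustment, decides little here. A pass takes at least 2 lists at its smallest p for PVAT minus LAD and 5 for differences with TA.

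Other splits of the samples show how often redrawn labels reach the real counts. Diet labels were redrawn over the pigs and not within sacrifice dates, so a split can follow a date. Of 100 splits of the LAD arrays, the real one included, 2 gave at least the real 4 probe sets (highest other 52), 5 at least the real 1720 at an unadjusted p under 0.05 (highest other 2125) and 18 at least the real 14 gene lists (highest other 18). Chance is thus less likely for the count of 4 but not excluded, since another split gave 52. It is not excluded for the other counts either. In PVAT 68 splits gave at least the real 221 at an unadjusted p under 0.05 (highest other 2952) and 33 at least the real 10 lists (highest other 18), and in TA 8 gave at least the real 720 (highest other 1293) and 44 at least the real 11 lists (highest other 19), so chance is not excluded for these. Without array 57 only 1, the real one, gave at least 29 (highest other 15). Chance is less likely there, in a fit chosen after the data were seen. Where the real count of probe sets is 0, all 100 splits reach it by construction, so the comparison decides nothing. The highest other counts there were 974 in PVAT, 1 in TA, 2 for LAD minus TA, 1 for PVAT minus LAD and 1007 for PVAT minus TA. For LAD versus TA only 1, the real one, reached 2458 (highest other 497), and for PVAT versus LAD only 1 reached 5677 (highest other 2546), so no other drawn split reached either count. Splits with far more calls than the real one, as 974 and 1007, point to a structure of the samples, and what it is was not tested.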

How the results depend on the processing

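Of the counts of probe sets and gene lists, 287 kept their size within 1.5 times and 65 moved. Of the named genes' differences under the alternatives, 2872 kept their call, 108 became stronger, 41 weaker and 28 moved. The 41 are the LAD calls of SMPDL3A, lost in 13 of 25 alternatives, SPP1 (14 of 26) and C1QA (14 of 26), whose differences kept their sign. The 28 are changes of sign of ADIPOQ in PVAT and TA, CCL2 and SCD in TA, and NOS3 and EDN1 in PVAT, none passing where the sign changed, while SCD in TA passed at 1.44 (adjusted p 0.0407) with the 28S/18S ratio as a covariate without array 57, and the cause was not tested except where fewer arrays or probe sets were used. The tests chosen only after the result was seen are those without array 57, with the cardiomyocyte mean as a covariate, with the platform's symbols and the exact test of lists. SMPDL3A ranged from 3.78 to 4.54 (adjusted p 0.00359 to 0.145), SPP1 from 1.93 to 2.51 (0.0104 to 0.145), C1QA from 1.48 to 1.75 (0.0086 to 0.145) and CTSS from 1.62 to 2.00 (0.00245 to 0.156). In LAD, against 4 probe sets, all 6 groups in 1 fit gave 69, the pig as a replicate block in that fit 90, that fit without array 57 153, the sacrifice date as a block 9, array weights 116 and an adjusted p under 0.1 21. The 28S/18S ratio as a covariate, only arrays with a ratio of at least 0.8, the cardiomyocyte mean as a covariate, no filter and the lowest 50% left out each gave 0. Leaving out 1 pig gave 0 to 106 (102 without pig 57, 106 without pig 81, 1 without pig 56). In PVAT, against 0, the fit of all groups gave 2, the replicate block 2, the fit of all groups without array 57 3, and leaving out 1 pig 0 to 1 (pig 56). In TA, against 0, the fit of all groups gave 60, the replicate block 57, the ratio as a covariate 547, only ratios of at least 0.8 10 and array weights 265. Leaving out 1 pig from all TA arrays gave 0 to 29. Without array 57 alone TA gave 29, with all groups in that fit 75, with the date as a block 23, and with the ratio as a covariate 266. Leaving out 1 more pig there gave 1 to 31. Differences between tissues, each 0, gave for LAD minus TA 1 with array weights and 1 with the replicate block without array 57, for PVAT minus LAD 2 with the pig as a fixed block, SMPDL3A among them, and for PVAT minus TA 4 with ratios of at least 0.8 and 10 with array weights. LAD versus TA gave 4139 with array weights against 2458. The gene lists that passed numbered 14 in LAD, with 0 under an estimated correlation and 6 under the exact test. They numbered 10 in PVAT (1 and 0, and without 1 pig as few as 6, without pig 55) and 11 in TA (0 and 0, 7 with the date as a block, and 7 (without pig 80) to 13 (without pig 57) when 1 pig was left out). They numbered 9 for LAD minus TA (0 and 0, as few as 5, without pig 51), 8 for PVAT minus LAD (2 and 0, 5 with the platform's symbols, as few as 5, without pig 51) and 7 for PVAT minus TA (0 and 0, 4 with the date as a block, 2 with the platform's symbols). They numbered 6 for LAD versus TA (0 and 12) and 14 for PVAT versus LAD (0 and 21). Since the deposited table holds only probe sets with a log2 signal of at least 6.64 in 11 arrays, genes with weaker signal over background cannot be judged.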

Other observations

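The correlations of diet differences between tissues and their comparison with other splits, and the RNA ratio by diet, were tests chosen only after the result was seen. Probe sets at an unadjusted p under 0.05 in the same direction were counted for each pair of tissues, beside the count that independent tissues would give. Between LAD and TA (without array 57), 213 probe sets were higher in both where 551 × 536 / 10029 gives 29.4, and 233 were lower in both where 1169 × 533 / 10029 gives 62.1. Between LAD and PVAT 69 were higher in both (551 × 141 / 10029 gives 7.75) and 27 lower in both (1169 × 80 / 10029 gives 9.32), and between PVAT and TA 71 (141 × 536 / 10029 gives 7.54) and 14 (80 × 533 / 10029 gives 4.25). The interferon genes RSAD2, ISG15 and IFIT1 and the cholesterol exporter ABCA1 were higher in all 3 tissues: RSAD2 was 1.84 higher in PVAT and 2.27 higher in TA without array 57, and ABCA1 1.39 in LAD, 0.78 in PVAT and 1.19 in TA without that array. The tissues come from the same pigs, so they are not independent, and an excess over these counts does not by itself exclude chance.

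The correlation over probe sets of the obese versus lean differences was 0.619 between LAD and TA without array 57, 0.361 between LAD and PVAT and 0.358 between PVAT and TA, where probe sets are not independent replicates. The same pigs were split in other ways, for pigs with both tissues and not within sacrifice dates. Of 100 splits, the real one included, 4 gave a correlation between LAD and TA as high as the real 0.598 (9 pigs, highest other 0.639, median 0.404). Chance is less likely there but not excluded, since another split gave a higher value. For LAD and PVAT 19 of 100 were as high as 0.361 (11 pigs, highest other 0.585, median 0.225), so chance is not excluded. For PVAT and TA 2 of 100 were as high as 0.336 (9 pigs, highest other 0.345, median 0.131), so chance is less likely there but not excluded either. The medians of the other splits lay above 0 in each case.

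Genes of nerve and Schwann cells, which the report leaves at 0 of 9 passing in the full TA set, rose in TA without array 57 for 4 of 9 members over the list alone, MBP by 1.10 among them (list mean 0.40, adjusted p = 0.271 with an estimated correlation). In the same fit PDE5A, the phosphodiesterase that breaks down cyclic GMP, fell by 0.44, the 1 of 18 vasoactive genes that passed over the list alone, and TXNIP, an inhibitor of thioredoxin and glucose uptake, rose by 0.44, with IGFBP2 and IGFBP3 the 3 of 19 insulin genes that passed. TNFRSF1B, a TNF receptor, rose by 0.47 with VCAM1, 2 of 9 NF-kB genes. SPP1 was 1.65 (SE 0.73) and CTSS 0.82 (SE 0.38) higher in TA without that array, neither passing. Within the sacrifice dates the differences were 3.29, 1.83 and 0.52 for SPP1, and 1.68, 1.66 and -0.04 for CTSS. The last of these dates held the obese arrays of pigs 81 and 85, with 28S/18S ratios of 0.61 and 0.57.

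The 28S/18S ratio was lower in obese than lean samples in each tissue without passing a two-sided exact permutation test: by -0.211 in LAD (p = 0.305), -0.147 in PVAT (p = 0.208) and -0.2 in TA (p = 0.476).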
